A study of Mus musculus with 6 samples.

How the data were processed

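Total RNA of primary mouse embryonic fibroblasts was measured on Affymetrix mouse expression arrays, which report an intensity for each probe set, a group of short probes that match a transcript. The 6 arrays fell into 3 genotypes at exon 2 of Cas (p130Cas, gene symbol Bcar1), with 2 arrays each. These were wild type, heterozygous for the deletion and homozygous for the deletion. Per the labels, every culture came from an embryo at 12.5 days post coitum out of crosses between heterozygotes, 2 µg of RNA was used for each array, and each genotype was represented by 2 embryos. The p-values therefore measure the spread between embryos and their cultures, and 2 embryos per genotype limit the precision.

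The deposited values were linear probe set intensities, with 45101 probe sets on each array. The scanner software, the summary of probes into probe sets and any scaling are not given in the sources used here. The median deposited intensity was 23.7 and 22.6 in the wild-type arrays, 25.0 and 27.3 in the heterozygote arrays, and 26.0 and 21.9 in the homozygote arrays. The values were read as linear because all were above 0 and the highest lay between 15930 and 17154 on the 6 arrays. No pair of arrays held the same data, since arrays of a genotype differed by a median of 0.34 log2 units in the wild type, 0.28 in the heterozygotes and 0.32 in the homozygotes.

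Intensities were converted to log2(intensity + 1.78), where the pseudocount was the 10th percentile of all intensities. A fold change on this scale understates the change of dim probe sets. The log2 medians of the arrays spanned 0.29, above the limit of 0.1 set beforehand, so the arrays were quantile normalized, which removes any overall shift between arrays. The 64 control probe sets were left out after normalization, and the upper 50% of the other 45037 probe sets by mean log2 intensity were tested, which left 22519. The lowest mean log2 intensity kept was 4.57.

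Probe sets were named from a platform annotation table, with symbols updated through Entrez identifiers in a table of the GRCm38.p6 assembly. Of the probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none, and the remaining 64 were controls. The named probe sets covered 18193 genes, of which 204 had an identifier that did not match the assembly table and kept their annotated symbol. Genes were named only from probe sets with 1 symbol. The assembly table was otherwise used only to find which genes neighbour Bcar1, within 10 Mb, because the sources used here name no genome build.

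The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each genotype, all 6 arrays in 1 fit, 3 residual degrees of freedom and 3.28 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. The comparisons were homozygotes against the mean of the wild-type and heterozygote means, homozygotes against each of these genotypes, and heterozygotes against wild type. Errors given with a log2 difference are its standard error (SE) from this fit, and errors given with a group level are the SD of 2 arrays.

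Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01, on the probe set with the highest mean of each gene. All 11373 genes with 1 symbol that passed the intensity filter were the background. The lists covered Cas signalling, integrins, extracellular matrix, matrix proteases, chemokines, actin and serum response factor (SRF) targets, proliferation, immediate early genes, interferon response, p53 targets, hypoxia, TGF-beta and BMP signalling, positional identity, ribosomal proteins, the neighbours of Bcar1, embryo sex and markers of 10 cell types. Lists with at least 3 measured genes were tested, which left 23. Erythroid and liver markers had 1 gene each above the filter and osteoblast markers had 0, so these lists were not tested. Each list was also tested with a correlation estimated from its own residuals.

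The genes named were Bcar1, its relatives Nedd9 and Efs, and the chemokine receptor Cxcr4. In the main comparison, up to 12 genes in each direction were added, which had to pass the threshold and have both homozygote arrays beyond the other 4. Since no gene passed, the places were filled by the smallest unadjusted p in each direction among genes whose arrays were separated in this way, leaving out predicted genes, and these genes are described by their values. The other comparisons added 5 genes in each direction by the same rule, and each list added the members with the smallest p. The design, the lists, the rule on separated arrays and most alternatives were fixed before the data were examined. More members were named from called lists than from lists that were not called, so that number depended on the result. Nedd9 and the Y-linked gene Ddx3y were not analysed here, and a further gene that the design named is not reported here.

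The alternatives were the deposited values without quantile normalization, no pseudocount or the 25th percentile (7.00) as pseudocount, no intensity filter or the upper 25% only, the mean over the probe sets of a gene, an intensity trend in the prior variance, the replicate number as a block, a covariate for embryo sex (the log2 level of Xist minus the mean of the Y-linked genes), leaving out each array, and fitting only the 4 arrays compared. The covariate for embryo sex was 5.87 and -2.93 in the wild-type arrays, 8.44 and 8.62 in the heterozygotes, and -3.88 and -2.24 in the homozygotes. Its slope therefore rests mainly on the difference between the wild-type arrays. With an array left out, the remaining array of its genotype was assumed to vary like the other genotypes.

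The procedure was tested on simulated arrays of 22519 probe sets with known changes in the homozygotes, in 20 runs. In the main comparison, limma recovered 1.3% of 2-fold changes, 67.0% of 4-fold changes and 96.9% of 16-fold changes, with 6.6 false calls per run on average. Each run mixed these sizes with 64-fold changes, and many large changes ease the adjusted threshold for smaller ones. The recovery of 4-fold changes therefore does not carry over to data with few large changes. Of simulated lists of 20 genes shifted by 1 log2 unit, 200 of 200 were called, and of unshifted lists 5 of 200 were called. The simulated genes were independent of each other, unlike the genes of a real list.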

Results

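Gene expression was profiled in primary fibroblasts of mouse embryos that carried 2, 1 or 0 intact copies of exon 2 of Cas. Cas (p130Cas, encoded by Bcar1) is a docking protein of integrin-based adhesions, which passes signals from Src-family kinases and focal adhesion kinase to the small GTPase machinery. The arrays came from 2 wild-type, 2 heterozygous and 2 homozygous embryos at 12.5 days post coitum. The stated aim was to compare homozygous cells with both other genotypes. The number of arrays limits the precision of every value.

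The targeted gene did not separate the genotypes. The Bcar1 probe set lay at 8.90 ± 0.68 in wild type, 8.25 ± 0.09 in heterozygotes and 8.25 ± 0.25 in homozygotes (log2 intensity, mean ± SD, n = 2). The difference of homozygotes from the other genotypes was -0.32 (SE 0.31, limma adjusted p = 1), and a second Bcar1 probe set also gave -0.32. The difference was -0.08 without wild type 1 and 0.58 with a covariate for embryo sex. Where these probe sets lie relative to exon 2 is not given in the sources used here, so they check nothing about the deletion. Efs, a relative of Cas, differed by 0.14 (SE 0.21), and its other probe set gave -0.32. Cxcr4, a chemokine receptor, lay below the intensity filter and was at 4.99 ± 0.04 in homozygotes, 3.45 ± 1.53 in heterozygotes and 2.90 ± 2.20 in wild type (difference 1.81, SE 1.03).

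The embryos differed in the expression of sex-linked genes, and the labels give no sex. Xist, the RNA that coats the inactive X chromosome, was at a log2 intensity of 8.82 in wild type 1, 10.27 and 10.29 in the heterozygotes, 4.23 in wild type 2, and 3.70 and 5.31 in the homozygotes. The Y-linked gene Eif2s3y had the opposite order, with 3.61 in wild type 1, 1.24 and 1.70 in the heterozygotes, 8.37 in wild type 2, and 8.76 and 8.61 in the homozygotes. Uty and Kdm5d, also on the Y chromosome, were low and high in the same arrays as Eif2s3y. Both homozygote arrays thus had the expression of male embryos and both heterozygote arrays that of female embryos, while the wild type held 1 of each. Genotype and sex cannot be separated between homozygotes and heterozygotes. Values given below with the covariate for embryo sex rest mainly on the difference between the wild-type arrays, of which wild type 1 stood apart. They cannot tell sex from other differences between these arrays.

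**Figure D1:**
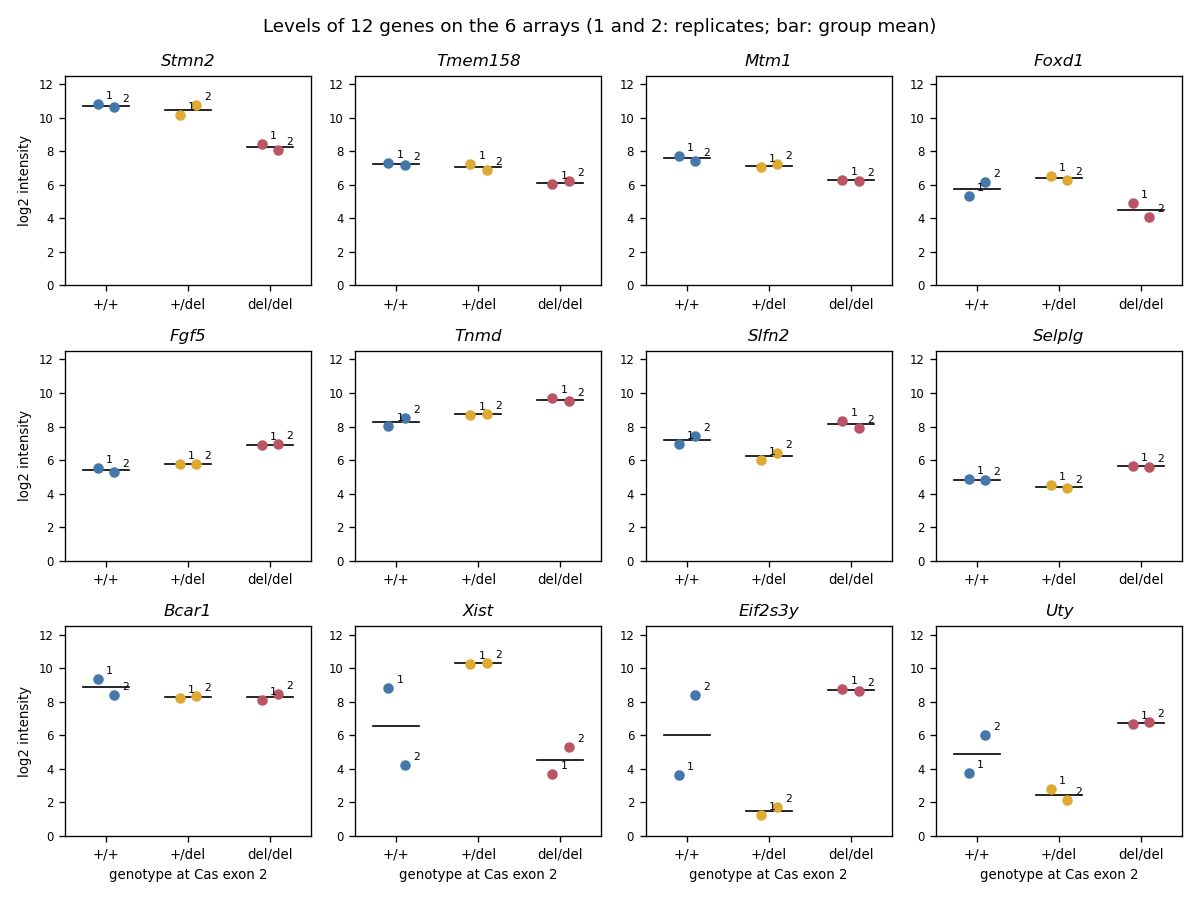
Log2 intensity after quantile normalization (vertical axis) of 12 genes on the 6 arrays, by genotype at Cas exon 2 (+/+ wild type, +/del heterozygote, del/del homozygote), where points are arrays numbered by replicate and bars are means of 2 arrays. Stmn2 lay at 8.46 and 8.08 in the homozygotes and between 10.19 and 10.82 on the other 4 arrays, and Xist and the Y-linked genes Eif2s3y and Uty split the wild-type pair.

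The main comparison set homozygotes against the wild type and heterozygotes together. Stmn2, a regulator of microtubules known from neurons, was the gene with the smallest p-value. It was 5.06-fold lower in homozygotes, at 8.27 ± 0.27 against 10.73 ± 0.12 in wild type and 10.48 ± 0.41 in heterozygotes (log2 difference -2.34, SE 0.25), but it did not pass the threshold (limma adjusted p = 0.70). A second Stmn2 probe set gave -2.29. Fgf5, a secreted fibroblast growth factor, was 2.51-fold higher, at 6.91 ± 0.06 against 5.40 ± 0.15 and 5.76 ± 0.04 (difference 1.33, SE 0.19, limma adjusted p = 1).

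In total, limma called 0 of 22519 probe sets in the main comparison. At an unadjusted p under 0.05 there were 560 probe sets, 274 higher and 286 lower, where chance alone gives 1126. Both homozygote arrays lay above the other 4 arrays for 359 of 11373 genes and below them for 411, where chance gives 758.2 in each direction. Without wild type 2, the male wild type by its sex-linked genes, 2 probe sets were called, Eif2s3y (log2 difference 6.14, limma adjusted p = 0.0111) and a probe set with no gene symbol (4.74, limma adjusted p = 0.0128), which were named here after their values were seen.

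None of the genes named by the rule on separated arrays passed the threshold (limma adjusted p = 1 for each gene of this paragraph). Among genes higher in homozygotes, Slfn2, a schlafen family gene of lymphoid and myeloid cells, differed by 1.43 (SE 0.26), Lyl1, a transcription factor of blood cells, by 1.03 (SE 0.18), and Selplg, the P-selectin ligand of leukocytes, by 1.01 (SE 0.18). Cd200r4, of a myeloid receptor family, differed by 1.25 (SE 0.28), Casp1, the inflammasome protease, by 1.17 (SE 0.28), and the interferon-induced gene Oas2 by 1.10 (SE 0.28). Tnmd, a tendon membrane protein, differed by 1.11 (SE 0.22), the transcription factor Tcf21 by 1.21 (SE 0.30) and Frmd4b by 1.50 (SE 0.36, with 0.30 from its other probe set), and the Y-linked genes Eif2s3y and Uty by 4.95 (SE 1.18) and 3.08 (SE 0.61). With the covariate for embryo sex, Frmd4b was at 0.52 (SE 0.47), Tcf21 at 0.49 (SE 0.43), Cd200r4 at 0.54 (SE 0.39) and Tnmd at 0.64 (SE 0.34), and Eif2s3y and Uty, which enter the covariate, were at 0.72 and 1.06. Without homozygote 1, Casp1 was at 0.74 and Oas2 at 0.67.

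Among genes lower in homozygotes, the transcription factor Foxd1 differed by -1.57 (SE 0.34), the transcriptional corepressor Cbfa2t3 by -1.53 (SE 0.36), and Fam71f1 by -1.38 (SE 0.31), each with limma adjusted p = 1. With the covariate for embryo sex, Foxd1 was at -2.44 (SE 0.47), and without homozygote 1 Cbfa2t3 was at -0.94. Genes of membrane proteins included Pllp (-1.21, SE 0.24), the R-spondin receptor Lgr6 (-1.06, SE 0.23), P-cadherin or Cdh3 (-1.04, SE 0.22), Tmem158 (-1.03, SE 0.20), the citrate transporter Slc13a5 (-0.95, SE 0.22) and the serine protease Tmprss6 (-0.95, SE 0.22). The lipid phosphatase Mtm1 differed by -1.10 (SE 0.20), with -1.24 and 0.48 from its other probe sets. Parpbp differed by -0.87 (SE 0.21), and another of its probe sets gave 0.23.

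Among gene lists, macrophage markers had the smallest adjusted p. All 19 measured markers were higher in homozygotes, with a median log2 difference of 1.26, and camera called the list higher (limma adjusted p = 9.25e-21 with the preset correlation). With an estimated correlation the call was lost (limma adjusted p = 0.388). Cd68 differed by 1.33 (SE 0.49), the leukocyte phosphatase Ptprc by 1.33 (SE 0.48) and the tetraspanin Cd53 by 1.24 (SE 0.41), and 0 markers passed alone, also when adjusted over the list alone. Arrays of a genotype also differed from each other, since the median level relative to the mean of the 6 arrays was -1.10 and 0.28 in wild type, -0.30 and -0.45 in heterozygotes, and 1.23 and 0.18 in homozygotes. Without wild type 1 the median difference of the list was 0.82. Without homozygote 1 the median was 0.59, with Cd68 at 0.64, Ptprc at 0.54 and Cd53 at 0.51. That difference rests on wild type 1 and the heterozygotes, since the level in homozygote 2 (0.18) lay below that in wild type 2 (0.28). With the covariate for embryo sex the call was lost, with a median of -0.20 (limma adjusted p = 0.391), and Cd68 was at 0.06, Ptprc at 0.33 and Cd53 at 0.64.

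Of the interferon response genes, all 15 measured were higher in homozygotes, with a median of 0.94 (limma adjusted p = 1.02e-11 for the list, and adjusted p = 0.388 with an estimated correlation). Rsad2 differed by 1.65 (SE 0.45, with 0.41 from its other probe set), Usp18 by 1.30 (SE 0.57) and the RNA sensor Ifih1 by 0.99 (SE 0.34). The list's level was 1.43 in homozygote 1 but -0.10 in homozygote 2, and the call was lost without homozygote 1 (0.19, limma adjusted p = 0.0606) and with the covariate for embryo sex, where the median was -0.17 (limma adjusted p = 0.794). Without homozygote 1, Rsad2 was at 0.91, Usp18 at 0.33 and Ifih1 at 0.50, and with the covariate Usp18 was at 0.04 and Ifih1 at 0.63. The interferon list was at -1.02 in wild type 1, its lowest array, and the macrophage markers were likewise lowest in wild type 1 (-1.10) and highest in homozygote 1 (1.23). Chemokines and their receptors had 10 of 16 genes higher, with a median of 0.27 (limma adjusted p = 0.00193, and adjusted p = 0.474 with an estimated correlation). Of these, Ccl2 differed by 1.05 (SE 0.31), Ccl7 by 1.00 (SE 0.35) and Ccl9 by 2.16 (SE 0.76). The chemokine call was lost without wild type 1 (limma adjusted p = 0.175) or homozygote 1 (limma adjusted p = 0.107), and with the covariate for embryo sex (-0.10, limma adjusted p = 0.181), where Ccl2 was at 0.58, Ccl7 at 0.09 and Ccl9 at 0.94. Ccl9 lay at 10.30 in homozygote 1 and 7.39 in homozygote 2, and without homozygote 1 its difference was 0.71. The chemokine list, like the macrophage markers, was lowest in wild type 1 (-0.63) and highest in homozygote 1 (0.33).

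Adipocyte genes were higher in homozygotes for 5 of 5 measured, with a median of 0.84 (limma adjusted p = 5.13e-06 for the list, and adjusted p = 0.291 with an estimated correlation). Lipoprotein lipase (Lpl) differed by 2.05 (SE 0.57), the fatty acid carrier Fabp4 by 0.70 (SE 0.23, with 0.42 from its other probe set) and the transcription factor Pparg by 0.84 (SE 0.40). Without Lpl and Cd36, which macrophages also express, the median was 0.70 (limma adjusted p = 0.00285). Macrophage expression of the genes left was not tested, so this does not separate the list from the macrophage markers. Adjusted over the list alone, 2 of the 5 genes passed, against 0 over all probe sets. The adipocyte call was made with any single array left out (limma adjusted p up to 0.00828) but not with the covariate for embryo sex (0.58, limma adjusted p = 0.111), where Lpl was at 0.58 and Pparg at 0.41. Without homozygote 1 Lpl was at 1.28, and without heterozygote 2 Pparg was at 0.50.

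Extracellular matrix genes were higher for 21 of 30, with a median of 0.07 (limma adjusted p = 0.0088, and adjusted p = 0.754 with an estimated correlation), among them decorin (Dcn, 1.50, SE 0.47), Thbs2 (0.81, SE 0.42) and periostin (Postn, 0.53, SE 0.26). Matrix proteases and inhibitors were higher for 14 of 18, with a median of 0.22 (limma adjusted p = 0.0126, and adjusted p = 0.561 with an estimated correlation). Their examples were Adamts1 (0.44, SE 0.28), Adamts5 (0.38, SE 0.22) and the macrophage elastase Mmp12 (1.75, SE 1.08), which lay at 9.25 in homozygote 1 and 4.90 in homozygote 2. Both calls were lost without wild type 1 (limma adjusted p = 0.380 for each), whose matrix genes lay at -0.56 relative to the mean of the 6 arrays. They were also lost without homozygote 1, and with the covariate for embryo sex the medians were -0.33 (called lower, limma adjusted p = 0.00256) and -0.48 (limma adjusted p = 0.111). Against heterozygotes alone, 24 of 30 matrix genes were lower, with a median of -0.11 (limma adjusted p = 0.286), and the proteases had a median of 0.0066 (limma adjusted p = 0.884), so neither list was called there. With the covariate Dcn was at -0.09, Thbs2 at -0.26, Postn at -0.17, Adamts1 at -0.11 and Adamts5 at 0.01. Without wild type 1 Thbs2 was at 0.53 and Postn at 0.33, and without homozygote 1 Thbs2 was at 0.51, Adamts1 at 0.06 and Mmp12 at -0.42.

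Proliferation genes were higher for 19 of 25, with a median of 0.14 (limma adjusted p = 0.0374, and adjusted p = 0.777 with an estimated correlation). Aurkb differed by 0.33 (SE 0.26), Pcna by 0.34 (SE 0.30) and Ccnb2 by 0.34 (SE 0.33). With the covariate for embryo sex the median was 0.30 and the list was still called higher (limma adjusted p = 0.00825). The list's level was 0.44 in homozygote 1 and -0.27 in homozygote 2. Without homozygote 1 the list was called lower, with a median of -0.23 (limma adjusted p = 0.000265) and Aurkb at 0.09, Pcna at -0.15 and Ccnb2 at -0.19, and the call was lost without wild type 2 (limma adjusted p = 0.892) or heterozygote 1 (limma adjusted p = 0.163), without quantile normalization (limma adjusted p = 0.0751) or the intensity filter (limma adjusted p = 0.0978), and against wild type (limma adjusted p = 0.0755) or heterozygotes alone (limma adjusted p = 0.177).

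Lower lists included neural and glial markers, with 8 of 10 genes lower and a median of -0.31 (limma adjusted p = 0.000205, and adjusted p = 0.291 with an estimated correlation). Besides Stmn2, the Schwann cell factor Sox10 differed by -1.61 (SE 0.61) and its target Erbb3 by -0.88 (SE 0.44), and 1 gene passed when adjusted over the list alone, against 0 over all probe sets. The call was lost without homozygote 2 (-0.19, limma adjusted p = 0.293), without the intensity filter (-0.22, limma adjusted p = 0.0699) and with the covariate for embryo sex (limma adjusted p = 0.118), where Sox10 was at -0.47 and Erbb3 at 0.48. Sox10 was at -0.62 without homozygote 1 and -2.60 without homozygote 2, and Erbb3 at -0.52 without wild type 1. Against heterozygotes alone the neural and glial median was -0.63. Of p53 targets and cell cycle inhibitors, 12 of 14 were lower, with a median of -0.19 (limma adjusted p = 0.014, and adjusted p = 0.474 with an estimated correlation), among them Perp (-0.78, SE 0.20), Cdkn1a (-0.34, SE 0.23) and Bbc3 (-0.33, SE 0.22). Of actin and SRF targets, 19 of 23 were lower, with a median of -0.15 (limma adjusted p = 0.0374, and adjusted p = 0.777 with an estimated correlation), among them Fhl1 (-0.81, SE 0.30), Lmod1 (-0.42, SE 0.35) and Flna (-0.33, SE 0.23). Without homozygote 1, the p53 median was -0.01 (limma adjusted p = 0.760) and the actin median 0.05 (limma adjusted p = 0.197), so neither list was called. There Cdkn1a was at -0.05, Fhl1 at -0.42, Flna at -0.07 and Lmod1 at -0.0023, and with averaged probe sets Fhl1 was at 0.03. The p53 call was also lost without wild type 2 (limma adjusted p = 0.111) or the intensity filter (limma adjusted p = 0.0745) and against wild type alone (limma adjusted p = 0.180). The actin call was lost without wild type 1 (limma adjusted p = 0.936), heterozygote 2 (limma adjusted p = 0.483), quantile normalization (limma adjusted p = 0.0654) or the filter (limma adjusted p = 0.128), and with averaged probe sets (-0.07, limma adjusted p = 0.397). Against heterozygotes alone, 14 of 23 actin targets were higher (0.04, limma adjusted p = 0.884). With the covariate for embryo sex the p53 call was lost (-0.37, limma adjusted p = 0.111) and the actin list was called higher (0.43, limma adjusted p = 0.00256), with Perp at -0.48, Bbc3 at -0.76, Fhl1 at -0.16, Flna at -0.10 and Lmod1 at 0.43.

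**Figure D2:**
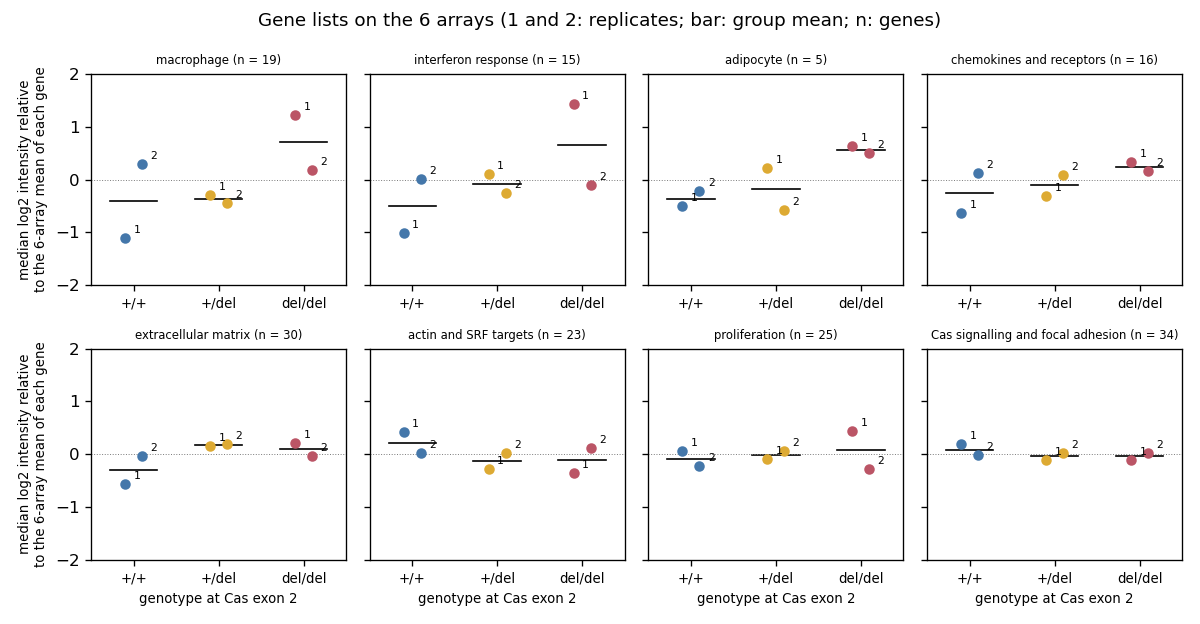
Median log2 intensity of the genes of 8 lists on each array, relative to the mean of each gene over the 6 arrays (vertical axis), by genotype at Cas exon 2, where points are arrays numbered by replicate, bars are means of 2 arrays and n is the number of genes. The macrophage markers spanned -1.10 to 0.28 within the wild type and 0.18 to 1.23 within the homozygotes.

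In total, camera called 11 of 23 lists in the main comparison with the preset correlation, 8 higher and 3 lower, and 0 with an estimated correlation. The embryo sex list was among the 8 called higher, with Xist at -3.90 (SE 1.20). Its median was 3.08 (limma adjusted p = 0.0302, and adjusted p = 0.388 with an estimated correlation), while its mean was 1.38. Xist and the Y-linked genes moved in opposite directions, so this call restates the sex of the embryos by these genes. This call was lost without homozygote 1 (limma adjusted p = 0.0723) or homozygote 2 (limma adjusted p = 0.248), against wild type alone (limma adjusted p = 0.184), and with the covariate for embryo sex (0.72, limma adjusted p = 0.0599), which is made from the same genes.

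Cas signalling and focal adhesion genes, the pathway of the targeted protein, were not called (limma adjusted p = 0.271). Of 34 genes, 21 were lower and 13 higher, with a median of -0.08, and Rapgef1, an exchange factor that binds Crk, differed by -0.50 (SE 0.22, with -0.18 from its other probe set, and -0.16 with the covariate for embryo sex). Without wild type 2 the list was called lower (-0.095, limma adjusted p = 0.0314). Integrins had a median of -0.10 (13 genes, limma adjusted p = 0.749), with Itga5 at -0.55 (SE 0.41). Itga5 was at -0.19 without wild type 1, -0.90 without wild type 2 and -0.02 with averaged probe sets. The 133 neighbours of Bcar1 had a median of -0.07 (limma adjusted p = 0.271), with Cdh3 at -1.04. The other lists that were not called were immediate early genes (-0.08, with Fosl1 at -0.49), hypoxia and glycolysis (-0.05, with Adm at 0.45), TGF-beta and BMP signalling (-0.06, with Id4 at 0.72), positional identity (0.02, with Tbx5 at 0.88), ribosomal proteins (0.01, with Rps6 at -0.12), and endothelial (0.26, with Flt1 at 0.63), skeletal muscle (0.28, with Myl4 at -0.40), cartilage (-0.11, with Col2a1 at -1.74) and epithelial markers (-0.40, with Perp at -0.78). Col2a1 was at -3.43 without homozygote 1 and -0.04 without homozygote 2, and other probe sets gave -0.43 to 0.71 for Flt1, 0.14 for Tbx5 and 0.33 for Rps6. Fosl1 was at -0.02 without wild type 1 and -0.96 without wild type 2. Without homozygote 1, Adm was at 0.27 and Id4 at 0.42. With single arrays left out, camera called cartilage markers lower without homozygote 1 (limma adjusted p = 0.00169), hypoxia lower without heterozygote 1 (limma adjusted p = 0.0221), epithelial markers lower without wild type 2 (limma adjusted p = 0.0239) or heterozygote 1 (limma adjusted p = 0.0314), endothelial markers higher without heterozygote 1 (limma adjusted p = 0.0441) or homozygote 1 (limma adjusted p = 0.0351), and positional identity higher without heterozygote 2 (limma adjusted p = 0.0300). The median and the mean of the TGF-beta list differed in sign (mean 0.03), as did those of the ribosomal list (mean -0.0045).

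Homozygotes were next compared with wild type alone. Stmn2 was 5.52-fold lower (log2 difference -2.46, SE 0.29, limma adjusted p = 0.840). Mtm1 (-1.32, SE 0.23), Aldh1a7, an aldehyde dehydrogenase (-1.49, SE 0.31), Ooep (-1.25, SE 0.27) and Tmem158 (-1.12, SE 0.23) were also named as lower. Fgf5 was 2.85-fold higher (1.51, SE 0.22), and Rimklb (3.08, SE 0.61), the transcriptional coactivator Ppargc1b (2.00, SE 0.41), Tnmd (1.33, SE 0.25) and Lyl1 (1.17, SE 0.21) were also named as higher. No gene passed (smallest limma adjusted p = 0.717). There were 855 probe sets at an unadjusted p under 0.05, 441 higher and 414 lower, fewer than the 1126 that chance alone gives. Camera called 9 lists, 6 higher and 3 lower, and 0 with an estimated correlation (smallest adjusted p = 0.501). Extracellular matrix genes had a median of 0.28 (25 of 30 higher, limma adjusted p = 1.15e-06, and adjusted p = 0.566 with an estimated correlation) and actin and SRF targets one of -0.28 (21 of 23 lower, limma adjusted p = 0.000618, and adjusted p = 0.704 with an estimated correlation). Relative to the mean of the 6 arrays, the matrix list lay at -0.562 in wild type 1 and -0.028 in wild type 2. It lay at 0.209 and -0.027 in the homozygotes. The actin list lay at 0.416 and 0.016 in wild type, and at -0.351 and 0.122 in homozygotes.

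Homozygotes against heterozygotes was also a comparison of male with female embryos by the sex-linked genes. Stmn2 was 4.65-fold lower (-2.22, SE 0.29), and Foxd1 (-1.88, SE 0.40), Pllp (-1.29, SE 0.27) and Tmem158 (-0.95, SE 0.23) were lower too, as was Xist (-5.77, SE 1.39). Slfn2 (1.92, SE 0.30), Selplg (1.22, SE 0.21) and Fgf5 (1.15, SE 0.22) were named as higher, with Eif2s3y (7.21, SE 1.36) and Uty (4.28, SE 0.70). No gene passed (smallest limma adjusted p = 1). At an unadjusted p under 0.05 there were 488 probe sets, 252 higher and 236 lower, fewer than the 1126 that chance alone gives. Fitting only the 4 arrays of these genotypes called 2 probe sets, Eif2s3y (limma adjusted p = 0.00653) and the same probe set without a gene symbol as above (log2 difference 5.01). For heterozygotes against wild type, without wild type 1 and homozygote 1, that probe set differed by -4.85 and Eif2s3y by -6.90. It thus moved with the Y-linked gene in both comparisons. Camera called 11 lists, 8 higher and 3 lower, and 0 with an estimated correlation (smallest adjusted p = 0.294). Positional identity genes had a median of 0.27 (22 of 28 higher, limma adjusted p = 2.29e-05, and adjusted p = 0.304 with an estimated correlation), and cartilage markers one of -0.81 (4 of 4 lower, limma adjusted p = 0.000331, and adjusted p = 0.294 with an estimated correlation).

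Heterozygotes against wild type gave the largest number of probe sets at an unadjusted p under 0.05 among the 4 comparisons, 1185 with 641 higher and 544 lower. This was close to the 1126 that chance alone gives, and limma called 0 (smallest adjusted p = 0.838). Rimklb was 9.20-fold higher in heterozygotes (log2 difference 3.20, SE 0.61), and the neuronal microtubule protein Map2 (2.48, SE 0.51), Tenm4 (1.91, SE 0.41), the retinol dehydrogenase Rdh5 (1.34, SE 0.27) and Pelp1 (1.00, SE 0.22) were also named as higher. Hcrt (-2.30, SE 0.40), the kinase Brsk1 (-1.99, SE 0.31), Aldh1a7 (-1.74, SE 0.31), the transporter Slc16a13 (-1.33, SE 0.21) and Zfp385c (-1.19, SE 0.23) were named as lower. Camera called 6 lists, 3 higher and 3 lower, and 0 with an estimated correlation (smallest adjusted p = 0.534). Extracellular matrix genes had a median of 0.59 (27 of 30 higher, limma adjusted p = 8.48e-08, and adjusted p = 0.534 with an estimated correlation) and positional identity genes one of -0.59 (20 of 28 lower, limma adjusted p = 1.41e-05, and adjusted p = 0.534 with an estimated correlation). Relative to the mean of the 6 arrays, the matrix list lay at -0.562 in wild type 1, -0.028 in wild type 2, and 0.158 and 0.195 in heterozygotes. Lists were tested with single arrays left out only in the main comparison. Without wild type 1, Eif2s3y alone was called (-6.90, limma adjusted p = 0.0264), and with the covariate for embryo sex Egfl6 alone was called (7.47, limma adjusted p = 0.0373), both named after their values were seen.

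Wild type 1 stood apart from the other 5 arrays. The log2 level of 1953 probe sets lay more than 1 from the mean of the other arrays there, against 361 in wild type 2, 842 and 315 in the heterozygotes, and 1052 and 409 in the homozygotes. Pearson's r across probe sets, which are not independent replicates, was 0.946 between the wild-type arrays, 0.968 between the heterozygote arrays and 0.955 between the homozygote arrays. Any comparison with wild type therefore carried this difference between the wild-type arrays.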

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

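All tests of explanations in this part were chosen after the results were seen, as was the rule that picked out the control probe sets. Ribosomal RNA probe sets, which are controls and entered no comparison, were bright in heterozygote 2. The 18S probe sets for the 3', 5' and middle parts lay at intensities of 313, 391 and 376 there, where the highest wild-type values were 130, 86.4 and 130. They were picked because they exceeded 2 times the highest wild-type value and an intensity of 100.

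Stmn2 was lower in the homozygotes (log2 difference -2.34), without passing the threshold. Fewer neural cells stay open as a source. The other 9 neural and glial genes had a median of -0.25 with an SD of 0.53, a smaller shift than that of Stmn2. Some were dim, with a mean log2 level of 4.75 for Sox10 and 5.22 for Erbb3, against 9.83 for Stmn2. Dimness did not hide the shifts of Sox10 (-1.61) and Erbb3 (-0.88). Without a pseudocount the median of the list with Stmn2 was -0.34, against -0.31 with it. The members moved unevenly, with 8 lower and 2 higher in the list with Stmn2, so a median cannot decide. The 9 genes without Stmn2 were also called lower as a list (limma adjusted p = 0.014 with the preset correlation). The list with Stmn2 lost its call at an estimated correlation (limma adjusted p = 0.291). With the covariate for embryo sex the difference was -2.24 (SE 0.47), but that fit rests mainly on the difference between the wild-type arrays. Wild type 2, male by its sex-linked genes, lay at 10.64 and wild type 1 at 10.82. This goes against embryo sex only as far as 1 wild-type embryo of each sex can show. The tables argue against cross-hybridisation of a single probe set, since the second probe set gave -2.29. An effect of the genotype remains a hypothesis, and chance is not excluded, because Stmn2 was picked as the smallest p-value among 22519 probe sets and its adjusted p was 0.70.

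Macrophage markers were higher in the homozygotes, with a median of 1.26. A macrophage share that varies between cultures of a genotype may account for it, since the markers differed by a median of 1.18 (SD of markers 0.52) between the wild-type arrays, with 19 of 19 higher in wild type 2, and by -0.88 from homozygote 1 to homozygote 2. Embryo sex may account for it too, since with its covariate the median was -0.20, within its typical SE of 0.51. Both tests rest on the difference between the wild-type arrays, so they are not independent and do not separate these explanations. A difference by genotype stays open, as untested apart from them.

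Wild type 1 stood apart, with a score of -75.6 on the first principal component, which held 44.1% of the variance. Embryo sex stays open. The test used the 1953 probe sets that lay more than 1 log2 unit from the other arrays in wild type 1. Over these, the heterozygote arrays, which share its high Xist, differed from the 3 arrays with low Xist by a median of -0.18 (SD over probe sets 0.62). Wild type 1 differed from those 3 arrays by 1.30, both signed by the direction in wild type 1. However, the other arrays used to pick these probe sets include the heterozygotes. The choice therefore favours probe sets where the heterozygotes do not follow wild type 1, and it makes the difference of wild type 1 large. This contrast cannot decide how far embryo sex contributes. The controls show no marked RNA degradation in wild type 1. The ratio of 3' to 5' signal was 1.14 for beta-actin, the lowest of the 6 arrays (the others spanned 1.24 to 1.39), and 0.820 for GAPDH, the highest (the others spanned 0.783 to 0.802). A small difference in RNA quality stays open, since these controls rank wild type 1 in opposite order. A difference in culture state between these embryos stays open and was not tested.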

How the results depend on the processing

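The alternative that leaves out wild type 1 and homozygote 1 together, lists with shared members removed and crossed replicate numbers were chosen after seeing the data. Calls stayed at 0 in homozygotes against wild type under every alternative. Leaving out 1 array at a time gave 0 to 2 calls in the main comparison, 0 to 2 against heterozygotes, 0 to 1 for heterozygotes against wild type, and 7 to 14 called lists (7 without wild type 1 or homozygote 1). Fitting only the 4 arrays gave 2 calls against heterozygotes. Leaving out wild type 1 and homozygote 1 together gave 4 calls for homozygotes against heterozygotes and 4 for heterozygotes against wild type, all of Eif2s3y, Xist and a probe set with no symbol. The embryo sex covariate gave 1 call for heterozygotes against wild type and 4 called lists, and an estimated correlation gave 0 lists against 11. The other settings gave 8 to 11 lists. The filter changes which lists can be tested. Without it, 26 lists were tested and 8 called, 7 of the main 23 and erythroid markers (-0.44, limma adjusted p = 0.0405). With the upper 25% 16 lists were tested, with averaged probe sets 20 and with no pseudocount 22, so 3, 2 and 1 of the called lists gave no value there. The cause was not tested, except that fewer arrays entered where some were left out.

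With the replicate number as a block, calls were 0 in all 4 comparisons and lists 11. Deviations of same-numbered arrays correlated at -0.36, -0.14 and -0.14, so same-numbered arrays did not deviate in the same direction. Crossed numbers gave 0 calls in the 3 comparisons of a pair of genotypes. These fits used 4 arrays each, with few residual degrees of freedom, so a batch that follows other pairings is not excluded.

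With the embryo sex covariate, medians turned to -0.33 for extracellular matrix, -0.48 for matrix proteases, -0.097 for chemokines, 0.43 for actin targets, -0.20 for macrophage markers, -0.17 for interferon response, 0.89 for immediate early genes (called higher), 0.37 for integrins, 0.12 for Cas signalling, 0.21 for hypoxia, 0.36 for epithelial markers and -0.018 for ribosomal proteins. Differences turned to -0.014 for Efs, 0.58 for Bcar1, 0.76 for Itga5, -0.088 for Dcn, -0.17 for Postn, -0.26 for Thbs2, -0.11 for Adamts1, 0.43 for Lmod1, 1.31 for Fosl1, 0.082 for Rps6, 0.48 for Erbb3, and 0.43 for Xist (0.45 against heterozygotes). Over single arrays left out, medians that turned spanned -0.15 to 0.011 for Cas signalling, -0.17 to 0.060 for integrins, -0.023 to 0.22 for extracellular matrix, -0.39 to 0.051 for actin targets, -0.23 to 0.48 for proliferation, -0.57 to 0.41 for immediate early genes, -0.21 to 0.17 for hypoxia, -0.15 to 0.093 for TGF-beta signalling, -0.14 to 0.15 for positional identity, -0.0066 to 0.018 for ribosomal proteins, -0.065 to 0.63 for endothelial, -0.042 to 0.40 for skeletal muscle and -0.50 to 0.046 for cartilage markers, and -0.17 to 0.049 for the neighbours of Bcar1. Differences that turned spanned -0.42 to 3.93 for Mmp12, -0.15 to 0.83 for Pcna, -0.19 to 0.88 for Ccnb2, -0.35 to 0.11 for Rps6 and -0.056 to 0.33 for Efs. Without wild type 1 and homozygote 1 together, extracellular matrix turned to -0.096, matrix proteases to -0.034, actin targets to 0.19, proliferation to -0.12, interferon response to -0.011, Cas signalling to 0.069, hypoxia to 0.16 and the neighbours of Bcar1 to 0.012. Averaging probe sets turned Efs to -0.088, Fhl1 to 0.029, Rps6 to 0.11, positional identity to -0.051 and ribosomal proteins to -0.0014. Without quantile normalization, extracellular matrix turned to -0.0088 (still called higher), positional identity to -0.022 and ribosomal proteins to -0.052, and without the filter skeletal muscle markers turned to -0.20 and epithelial markers to 0.11. Against heterozygotes alone, medians were -0.11 for extracellular matrix, 0.042 for actin targets, 0.065 for integrins, 0.048 for immediate early genes, 0.091 for hypoxia, -0.00078 for ribosomal proteins and 0.16 for epithelial markers. Against wild type alone they were 0.026 for integrins, 0.041 for immediate early genes, 0.12 for TGF-beta signalling, -0.054 for positional identity, -0.0055 for ribosomal proteins, -0.018 for endothelial, -0.049 for skeletal muscle and 0.30 for cartilage markers. The cause was not tested.

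Of the other values, 301 for single lists kept the sign of the median and the side of the threshold (for 13 of them camera's direction turned, with no call), 44 lost the call and 19 gained it. For single genes 1348 kept both and 4 gained a call. Some alternatives, such as the intensity trend and the replicate block, cannot change a log2 difference or a list median. An estimated correlation cannot change a list median either. Signs kept there were fixed in advance, so these counts overstate the stability. Stmn2 lay between -2.53 and -2.15 over its alternatives in the main comparison, with adjusted p from 0.188. Dim probe sets limit the precision, since many named genes lay near the lowest mean kept, 4.57.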

Other observations

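The genes furthest from the other arrays in wild type 1, 10 in each direction, were listed by size after the arrays were seen, and they are given as log2 levels in wild type 1 against the mean of the other 5 arrays. Ankrd1, a target of mechanical and serum signals, was at 10.89 against 6.90, skeletal actin (Acta1) at 11.54 against 8.27, and the prostaglandin synthase Ptgs2 at 11.76 against 8.95. Crct1 and Lce1h, genes of the cornified layer of the epidermis, were at 8.29 against 5.11 and 9.03 against 6.25, and the median level of the epithelial list was highest in wild type 1, at 0.46 relative to the mean of the 6 arrays, where the others spanned -0.62 to 0.14 (5 genes). The phosphatases Dusp5 and Dusp4 were at 7.89 against 4.71 and 8.33 against 5.95, the natriuretic peptide Nppb at 7.58 against 4.96, Siglecg at 8.65 against 6.19 and Tmcc3 at 10.14 against 7.72. In the other direction, Gas1, a gene of growth-arrested cells, was at 7.46 against 11.92, Egfl6 at 1.77 against 7.70, Scara5 at 1.39 against 6.98, Tmem178 at 1.12 against 6.67, Olfml1 at 1.23 against 6.60, Sned1 at 2.15 against 6.99, Scg2 at 1.48 against 6.30, Gbp6 at 2.169 against 6.501, Lrrtm3 at 1.25 against 5.51 and Ecrg4 at 4.78 against 8.88.

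Immediate early genes differed between the arrays of every genotype. Their median level relative to the mean of the 6 arrays was 0.47 and -0.65 in wild type, -0.58 and 0.48 in heterozygotes, and 0.41 and -0.53 in homozygotes. The list was not called in the main comparison. With the preset correlation, camera called it lower without homozygote 1 (median -0.57, limma adjusted p = 4.58e-05), wild type 2 (-0.32, limma adjusted p = 0.0255) or heterozygote 1 (-0.34, limma adjusted p = 0.0314), and higher without homozygote 2 (0.41, limma adjusted p = 0.00685) or with the covariate for embryo sex (0.89, limma adjusted p = 0.00256).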
